A study of Caenorhabditis elegans with 6 samples.

How the data were processed

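RNA was measured by short-read sequencing in 6 libraries of whole Caenorhabditis elegans worms of the N2 strain, 3 from worms given D-mannose and 3 from worms given water, all harvested at an age of 6 days. Per the labels' protocols, the worms grew on plates seeded with the Escherichia coli strain OP50, RNA was taken with Trizol, and TruSeq and VAHTS kits are both named for the libraries; which library was made with which kit is not given in the sources used here. Per the submitters' processing notes, adapters were trimmed with cutadapt, reads were inspected with FastQC and aligned with HISAT2 2.1.0 to WBcel235. The counting tool, its strand setting and its treatment of reads that fall on several genes are not given in the sources used here.

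The deposited tables hold 1 value per gene for 47656 genes, with each gene's position, length and name. The values deposited by the authors are FPKM, fragments scaled by the listed gene length and by an effective library size. The unit was worked out from the values: a value multiplied by the gene length was a whole multiple of 1 step per library, within 0.05 of a read, for 95.0% to 95.8% of the values worth up to 20 reads and for 86.7% to 87.2% of all values above 0. The other values are fractions of a read. The step gives effective library sizes of 38000000 to 49400000 reads after rounding, and the ratio of that size to the summed reads differed by at most 0.00032 from trimmed-mean (TMM) scaling factors recomputed from the same reads. The summed read equivalents were 39900000 to 46000000 per library after rounding, and 1 read in a gene of 1 kb was worth 0.0202 to 0.0263 FPKM. For 1927 genes all 6 tables hold no value, 1911 of them pseudogenes and 12 of them genes of the mitochondrial genome, and the list of mitochondrial transcripts had 0 measured members under the names fixed for it and was not analysed here. The mitochondrial ribosomal RNA genes do have values, under names that are in no list: s-rRNA had 0 FPKM in mannose 2 and 39.7 to 69.4 in the others, and l-rRNA had 19.3 to 40.0 FPKM; both were tested as genes. A further 23983 genes are listed at 0 in all 6 libraries. Of the genes, 45774 were matched by locus tag to the RefSeq gene table for WBcel235, and 83.8% of those have the same start and end there; positions printed are those of the deposited tables.

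Because the values are not counts, the count-based test planned for count tables was replaced by the one planned for normalized values. Genes with an FPKM of at least 1 in at least 3 of the 6 libraries were tested, 11237 in all, with limma 3.58.1 (trend and robust settings, R 4.3.3) on log2(FPKM + 1). The threshold was a Benjamini-Hochberg adjusted p of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. The tests were run on simulated data first. With 200 of 11237 genes changed in independent simulated libraries that had the median spread of the real genes, 195 to 200 of the changed genes were recovered at a fold of 2 over 20 draws, with 3 to 20 other genes called. In the same kind of test, a list shifted by 0.5 log2 units was called by each of the 3 list tests below, and 0 of the other lists were. Its genes were drawn independently of each other, so it does not show how the list tests behave where members vary together. In the real libraries the estimated correlation between members was 0.49 for cuticle collagens and 0.65 for sperm genes.

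Gene lists, the rule for naming genes, the groups and most alternatives were fixed before the data were examined. The filter on low values was set once the unit was known. Some lists share members, so their calls are not independent of each other. The glycosyltransferase list takes every gly and fut gene and so holds all those of the N-glycosylation list, gly-12 among them. The glutathione S-transferase list takes every gst gene and so holds all those of the oxidative stress list, gst-10 and gst-30 among them. Of 47 lists, 46 had at least 5 measured members. Each was tested with camera, two-sided, with a preset correlation between genes of 0.01, and again with the correlation estimated from the data and with fry; p-values were adjusted over the 46 lists. Symbol families with at least 10 tested members were to be tested for enrichment among called genes with a one-sided Fisher exact test. Shares of reads were compared with a two-sided exact permutation test of 3 libraries against 3, whose smallest possible p is 0.1. The rule named the 12 genes with the largest change in each direction among genes past the threshold whose groups do not overlap and whose mean FPKM is at least 5 in the higher group (none passed), up to 4 members with the smallest p from each list described, and 9 genes of hexose entry whatever their p. Genes that overlap another expressed gene model on the same strand are named as such, since their reads may be divided between models.

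The alternatives set before the data were seen, for genes and in part for lists, were median-of-ratios and upper-quartile scaling computed on the FPKM, other filters, another pseudocount, limma-voom on the read equivalents, a test against a log2 fold change of 1, the replicate number as a block, and leaving out each library in turn. Alternatives chosen after seeing the data were leaving out mannose 1 and water 3 together, a model term for those libraries, removal of each library's trend with gene length, leaving out genes that overlap another on the same strand, a pseudocount of 0.5 for genes, and for lists upper-quartile scaling, the looser filters and a pseudocount of 0.1. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. Python 3.11.15 with pandas 2.3.3 read the tables and matplotlib 3.10.9 drew the figures.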

Results

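The data set compares the transcriptomes of whole N2 worms, the standard laboratory strain of Caenorhabditis elegans, given the hexose D-mannose or water. Each group holds 3 libraries of worms aged 6 days. The libraries held 39900000 to 46000000 read equivalents each after rounding, and 17819 to 18509 genes had a value above 0. Spearman correlations over 11237 expressed genes lay between 0.940 and 0.987 within groups and between 0.933 and 0.985 between groups, so libraries of one group were not closer to each other than to those of the other. The closest pair, water 1 and water 2, differed by 10.56 times the variance of sampling noise.

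Genes of the oocyte and germline differed widely between libraries, and this difference ran across the treatment groups. The first principal component held 67.2% of the variance. It placed mannose 1 (score −41.7) and water 3 (−48.2) away from the other 4 libraries, whose scores ran from 7.68 to 32.95. The 45 measured oocyte and germline genes lay a median of 0.87 and 0.78 log2 units above their mean over the 6 libraries in mannose 1 and water 3, against −0.71 to 0.02 in mannose 2, mannose 3, water 1 and water 2. Between the treatment groups the list had a median log2 difference of 0.10 and was not called (camera adjusted p = 0.52). This rested on single libraries: the list was called with the preset correlation without mannose 3 (median 0.50, adjusted p = 0.0060), without water 3 (0.60, adjusted p = 0.00039) and without both mannose 1 and water 3 (0.16, adjusted p = 0.037), and its median was −0.19 without mannose 1, −0.11 without water 1 and −0.023 without water 2. In the 3 fits that called it, the adjusted p was 0.79, 0.80 and 0.96 with an estimated correlation. Among its members with the smallest p, the germline Notch receptor gene glp-1 had 42.4 ± 20.8 FPKM in mannose and 26.3 ± 9.30 in water (SD, n = 3), and syp-4, of the synaptonemal complex, had 53.0 ± 10.5 and 41.4 ± 5.91. The second component, with 13.1% of the variance, had scores of −19.7 to −4.28 in mannose and 7.40 to 19.2 in water.

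**Figure D1:**
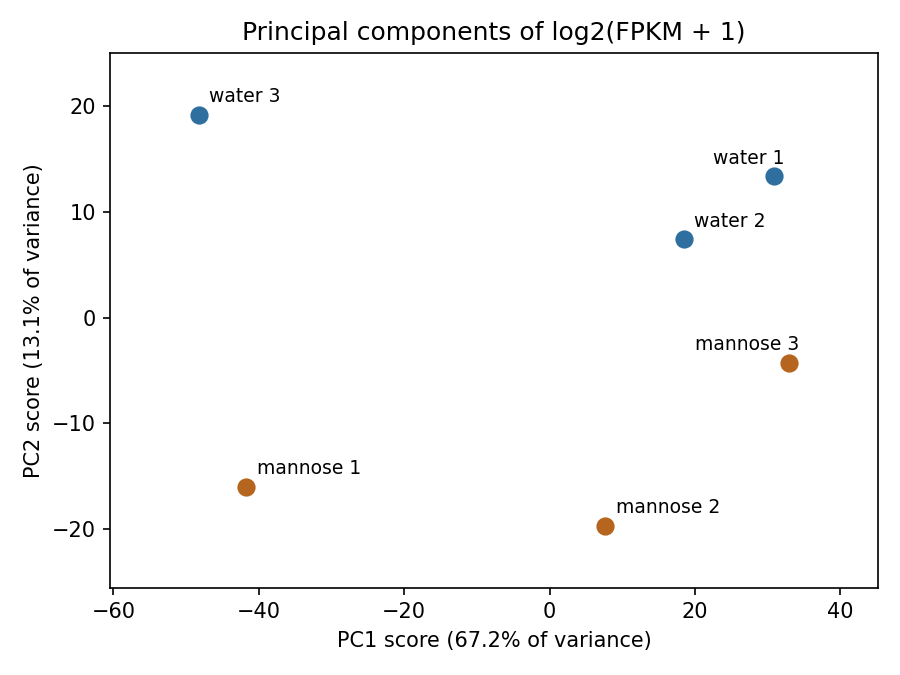
Scores of the 6 libraries on the first (x axis) and second (y axis) principal components of log2(FPKM + 1), each point a library and each colour a group. Mannose 1 and water 3 lie at −41.7 and −48.2 on the first component, and the other 4 libraries lie above 7.

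The comparison of mannose with water asks which transcripts differ in worms fed the sugar. The genes through which mannose enters metabolism were not called between the groups by the test adjusted over all genes. That test mostly missed changes of 2-fold added to these libraries. ZK632.4, the predicted mannose-6-phosphate isomerase (chromosome III, 9805515 to 9807454), had 133.1 ± 1.403 FPKM in mannose and 123.1 ± 12.9 in water (SD, n = 3), a log2 difference of 0.12 with a standard error of 0.12. Its groups did not overlap (131.9 to 134.6 FPKM in mannose, 108.3 to 131.4 in water), as was the case for 10.7% of all tested genes. The predicted phosphomannomutase F52B11.2 (IV, 14083568 to 14084695) had 41.4 ± 3.87 and 42.2 ± 2.81 FPKM, a log2 difference of −0.031 with a standard error of 0.13. The gene tag-335, which encodes a GDP-mannose pyrophosphorylase (IV, 12276090 to 12278594), had 44.6 ± 6.16 and 42.3 ± 2.66 FPKM. Its log2 difference was 0.069 with a standard error of 0.15. The standard errors of ZK632.4, F52B11.2 and tag-335 were small against a log2 difference of 1, which is a 2-fold change. None of the 9 genes of hexose entry passed the test, and the limma adjusted p of each was 0.9999.

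The hexokinase and hexosamine genes varied more between libraries of a group than between groups. The hexokinases had 113.5 ± 35.9 FPKM in mannose and 128.4 ± 40.8 in water for hxk-1, 25.9 ± 11.1 and 26.4 ± 12.4 for hxk-2, and 24.9 ± 6.56 and 23.6 ± 9.13 for hxk-3. Glucose-6-phosphate isomerase, gpi-1, had 31.4 ± 10.98 and 28.8 ± 9.15 FPKM. The gene gfat-1, for the enzyme that opens the hexosamine pathway, had 196.4 FPKM in mannose 1 and 257.6 in water 3 but 28.4 to 54.9 in the other 4 libraries. Its paralog gfat-2 had 428.5 ± 155.1 FPKM in mannose and 396.9 ± 127.3 in water. F52B11.2, hxk-2, hxk-3 and gpi-1 overlap other expressed gene models on their strand. Of the 22 measured genes of mannose and nucleotide sugar metabolism, 11 were higher and 11 lower in mannose, with a median log2 difference of 0.03 (camera adjusted p = 0.52). The median was 0.15 without mannose 3, 0.065 without water 3 and 0.012 to 0.015 without mannose 2, water 1 or water 2, and the list was not called in any of these fits. The member with the smallest p, the O-GlcNAc transferase gene ogt-1, had 26.4 ± 4.76 FPKM in mannose and 16.9 ± 2.62 in water, and it did not pass the test over all genes or adjusted over the list alone.

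**Figure D2:**
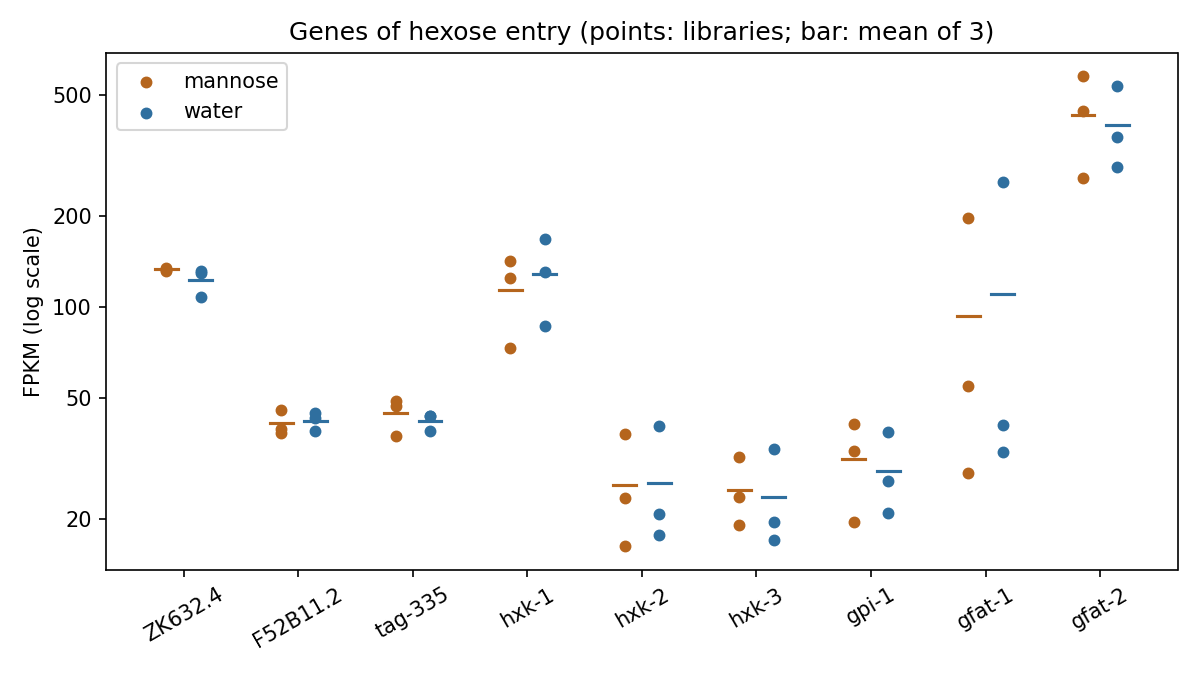
FPKM on a log scale (y axis) of the 9 genes of hexose entry (x axis) in each library, with points for libraries and bars for group means. ZK632.4 lies at 133.1 FPKM in mannose and 123.1 in water, and gfat-1 spreads from 28.4 to 257.6 FPKM across the 6 libraries.

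Over all genes, 0 of 11237 passed an adjusted p of 0.05 with limma, and 532 had an unadjusted p under 0.05, where 561.9 are expected by chance. Limma-voom on read equivalents also called 0 genes, with 535 at an unadjusted p under 0.05. With a model term for mannose 1 and water 3, chosen after the data were seen, limma called 0 genes and 1453 had an unadjusted p under 0.05, and without both libraries it called 3, with 713. The groups did not overlap in 1206 genes (10.7%), where chance gives 10%. The lowest adjusted p was 0.88, for C08E8.10 (chosen after its values were seen), with 0.873 ± 0.0738 FPKM in mannose and 2.90 ± 0.347 in water. Without mannose 1 limma called 2 genes, linc-44 and dml-1, both lower in mannose; dml-1 overlaps another expressed gene model on its strand. With no gene called, 0 of 95 symbol families were enriched. The median standard error of a log2 fold change was 0.18. When 200 genes were changed by a known fold in these libraries, 149 to 172 were recovered at a fold of 4 and 0 to 54 at a fold of 2, over 20 draws. Most changes of 2-fold thus did not pass the threshold adjusted over all genes. For a single gene the 95% interval of the log2 fold change reached a median of 0.44 to each side of the estimate.

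Cuticle collagen genes, which build the worm's outer covering, were lower in mannose as a list under the preset correlation. Of 108 measured, 98 were lower, with a median log2 difference of −0.52 (camera adjusted p = 7.2e-29 with the preset correlation). With the correlation between genes estimated from the data the list was not called (adjusted p = 0.73), nor was it with fry (adjusted p = 0.72). The abundant collagen gene col-20 (II, 4868807 to 4870791) had 2766 ± 199 FPKM in mannose and 3753 ± 249 in water, and col-142 (V, 6831177 to 6832256) had 255.5 ± 49.2 and 430.4 ± 60.5. The gene col-92 (III, 10982139 to 10987702) had 106.3 ± 13.3 and 176.4 ± 29.1 FPKM. By contrast dpy-14 had 4.97 ± 0.541 and 2.22 ± 0.667 FPKM. None of the members passed the limma test over all genes or adjusted over the list alone, and 43 had an unadjusted p under 0.05. The genes col-20 and col-92 overlap other expressed gene models on their strand. Median deviations from the mean of the 6 libraries were −0.25, −0.33 and −0.13 in mannose 1, 2 and 3 and 0.10, 0.01 and 0.74 in water 1, 2 and 3. The difference was −0.29 without water 3, −0.28 without mannose 1 and water 3 and −0.35 without a filter on low values.

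Sperm genes, among them those of the major sperm proteins that form the cytoskeleton of the crawling sperm, were also lower in mannose as a list under the preset correlation. Of 50 measured, 47 were lower, with a median log2 difference of −0.56 (camera adjusted p = 1.5e-20 with the preset correlation). The call was lost with an estimated correlation (adjusted p = 0.73) and with fry (adjusted p = 0.74). The small sperm-expressed genes nspd-2 (IV, 9844060 to 9844272) and nspd-7 (IV, 10268975 to 10269187) had 85.5 ± 6.63 and 53.2 ± 4.23 FPKM in mannose against 143.4 ± 6.77 and 84.5 ± 4.22 in water. No member passed the limma test over all genes, and 2, nspd-2 and nspd-7, passed when adjusted over the list alone. The genes nspd-3 and ssp-31 had 38.6 ± 7.13 and 11.6 ± 1.48 FPKM in mannose against 62.4 ± 4.13 and 18.5 ± 2.87 in water. Genes of these families are near-identical copies, so values of single members are uncertain. The groups overlapped: the list lay at 0.19, −0.63 and −0.35 in mannose 1, 2 and 3 and at 0.06, 0.11 and 0.59 in water 1, 2 and 3. The overlap depended on the scaling of the libraries: as a share of reads, mannose 1 (0.0821%) lay below water 1, 2 and 3 (0.0928% to 0.104%). The difference was −0.35 without mannose 2 and −0.37 without water 3.

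**Figure D3:**
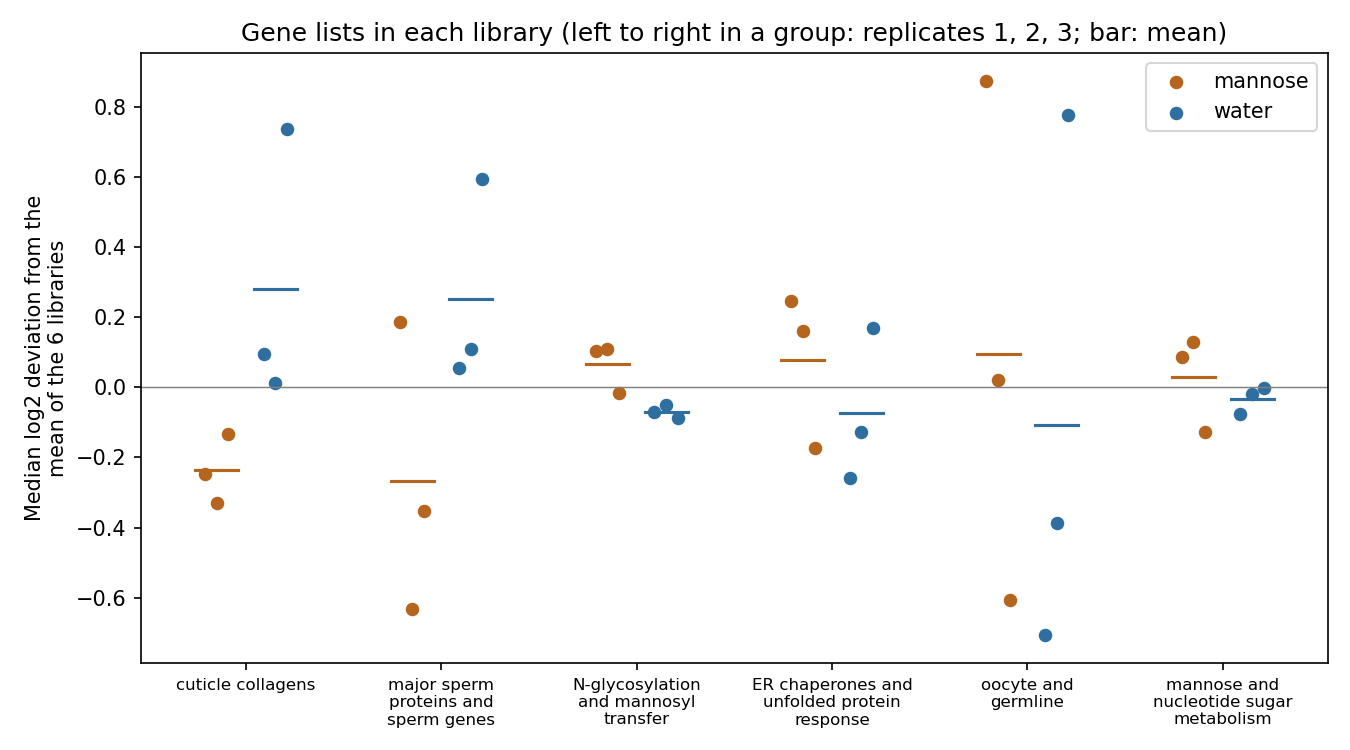
Median log2 deviation of each gene list's members from their mean over the 6 libraries (y axis) for 6 gene lists (x axis), with a point per library, replicates 1 to 3 from left to right, and a bar for the group mean. The 3 mannose libraries lie below the 3 water libraries for cuticle collagens, while mannose 1 and water 3 lie at 0.87 and 0.78 for oocyte and germline genes.

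Lists of the secretory pathway and of protein folding rose slightly in mannose under the preset correlation. N-glycosylation and mannosyl transfer genes had 31 of 38 members higher (median log2 difference 0.13, camera adjusted p = 0.0079), and the glycosyltransferase families had 20 of 26 higher (0.15, adjusted p = 0.016). ER chaperone and unfolded protein response genes had 29 of 38 higher (0.14, adjusted p = 0.013), and heat shock genes had 25 of 35 higher (0.16, adjusted p = 0.036). With an estimated correlation the adjusted p was 0.73 for the N-glycosylation, ER and heat shock lists and 0.60 for the glycosyltransferases. The Golgi mannosidase gene aman-2 had 22.5 ± 2.05 FPKM in mannose and 15.1 ± 3.09 in water, and algn-6, which adds glucose to the lipid-linked glycan, had 28.2 ± 2.60 and 20.9 ± 0.774. The ER stress kinase gene pek-1 had 9.85 ± 1.304 and 6.23 ± 0.701 FPKM, and hsp-70 had 50.9 ± 9.59 and 33.4 ± 11.34. None of these members passed the test over all genes or adjusted over its list alone. The N-glycosylation call ended without mannose 2 (median 0.093) or water 3 (0.12), and the median was 0.077 without mannose 1. The glycosyltransferase call ended without mannose 2 (0.10), water 2 (0.12) or water 3 (0.13). The ER list was not called without mannose 1 (0.098), mannose 2 (0.12), water 1 (0.093) or water 2 (0.083), and its median was 0.28 without mannose 3 and 0.29 without water 3. Its groups overlapped, with 0.25, 0.16 and −0.17 in mannose 1, 2 and 3 and −0.26, −0.13 and 0.17 in water 1, 2 and 3. Mannose 1 and water 3 were thus the highest, but the list was still called without both (median 0.18). The heat shock list was not called without mannose 1 (0.018), mannose 2 (0.11) or water 2 (0.12), and its median was 0.24 without mannose 3 and 0.052 without water 1. With each library's trend with gene length removed, the N-glycosylation (median 0.062, adjusted p = 0.094) and glycosyltransferase (0.080, adjusted p = 0.12) lists were not called, and the ER median was 0.071. With the stricter filter on mean reads the N-glycosylation (adjusted p = 0.059), glycosyltransferase (0.15) and heat shock (0.12) lists were not called. Nor was the heat shock list with upper-quartile scaling (adjusted p = 0.078) or with a term for mannose 1 and water 3 (0.093). Upper-quartile scaling gave medians of 0.074 for N-glycosylation, 0.10 for glycosyltransferases, 0.086 for the ER list and 0.097 for heat shock genes, and the glycosyltransferase median was 0.070 without a filter.

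The 10 other lists called with the preset correlation were lower in mannose, with medians of −0.14 to −0.07 apart from ribosomal RNA (−0.62). Glutathione S-transferases had 24 of 28 members lower (median log2 difference −0.14, camera adjusted p = 0.00020) and metal and iron handling genes 13 of 18 (−0.13, adjusted p = 0.0022). With an estimated correlation none of these 10 lists was called: the adjusted p was 0.60 for the metal handling and oxidative stress lists, 0.83 for the lipid binding list and 0.73 for the other 7. The metallothionein gene mtl-2, which overlaps 3 other expressed gene models on its strand, had 55.0 ± 14.9 FPKM in mannose and 88.5 ± 17.3 in water. Ribosomal protein genes had 62 of 77 lower (−0.11, adjusted p = 0.0016), but the call was lost without water 3 (median 0.075, camera adjusted p = 0.80). Their median was −0.041 without mannose 3, −0.20 without mannose 1 and −0.18 without water 1. Mannose 1 (0.23) and water 3 (0.34) lay highest for this list, against −0.16 to −0.077 in the others. Body wall muscle genes had 30 of 35 lower (−0.13, adjusted p = 0.0028), a call lost without mannose 1 (−0.051), with −0.22 without mannose 3; the myosin heavy chain gene unc-54 had 91.4 ± 18.4 and 121.1 ± 27.2 FPKM. The medians were −0.62 for 5 ribosomal RNA genes (adjusted p = 0.0053), −0.10 for 34 oxidative stress genes (0.0069), −0.08 for 67 C-type lectins (0.0079), −0.08 for 61 lipid binding genes (0.012), −0.07 for 38 cytochrome P450 genes (0.013) and −0.08 for 41 nuclear genes of oxidative phosphorylation (0.036). Ribosomal RNA took 0.198% to 0.474% of reads, and the 5 genes had an estimated correlation of 0.89, so they are far from separate measurements. Its share was planned as a description of the composition and RNA quality of the libraries. The call of this list is therefore not read as a change in the worms. On the scaled values the groups overlapped for this list, with 0.17 in mannose 1 and 0.013 and −0.038 in water 1 and 2. The ribosomal RNA call ended without mannose 3 (−0.34) or water 3 (−0.30), and that of the oxidative stress genes without mannose 1 (−0.092) or water 2 (−0.061), with −0.060 without water 1 and −0.17 without water 3. The lectin call ended without mannose 1 (−0.011) or water 1 (−0.062), without a filter (−0.0092, adjusted p = 0.62) and with a mean of at least 10 read equivalents (−0.051, adjusted p = 0.064), and that of the P450 genes without mannose 1 (−0.069) or water 1 (0.00058), with −0.033 without mannose 2 and −0.17 without water 3. The lipid binding call ended without mannose 1 (0.020), water 1 (−0.0075) or water 2 (−0.065), with −0.17 without mannose 3 and −0.15 without water 3. The oxidative phosphorylation call ended without mannose 2 (−0.048), mannose 3 (−0.025) or water 3 (0.035), with −0.17 without mannose 1 and −0.15 without water 1, and it ended without genes that overlap another on the same strand (adjusted p = 0.066). The glutathione S-transferase median was −0.24 without water 3. The groups overlapped for this list too, with 0.044 in mannose 3 and −0.053 in water 3, and 0 of its 28 members had an unadjusted limma p under 0.05. With length trends removed the ribosomal protein (−0.044, adjusted p = 0.36), lipid binding (−0.010, adjusted p = 0.73) and oxidative phosphorylation (−0.051, adjusted p = 0.053) lists were not called, and the medians were −0.22 for muscle and −0.047 for oxidative stress genes. With upper-quartile scaling the lipid binding list was not called (−0.14, adjusted p = 0.058), and the medians were −0.17 for ribosomal proteins, −0.16 for oxidative stress genes, −0.14 for lectins, −0.11 for P450 genes and −0.14 for oxidative phosphorylation. With an estimated correlation none of the 46 lists was called, with adjusted p from 0.60 to 0.99. Of the 16 lists called, 4 (collagens, sperm genes, glutathione S-transferases and metal handling) held their call and direction in each of the 6 fits that left out 1 library, and 10 held them without mannose 1 and water 3. The calls that ended without mannose 1 and water 3 were those of muscle (−0.033), lectin (−0.029), oxidative phosphorylation (−0.021), N-glycosylation (0.11), glycosyltransferase (0.14) and heat shock genes (0.14), and the medians were −0.069 for ribosomal proteins and −0.12 for P450 genes. The 30 lists not called had median log2 differences of −0.11 to 0.10 (camera adjusted p = 0.056 to 0.98). In the intracellular pathogen response list, skr-5, with 0.855 ± 0.0729 FPKM in mannose and 1.67 ± 0.148 in water, passed when adjusted over the list alone but not over all genes.

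Yolk protein genes were not called as a list, and the share of reads they took was close in both groups. The 6 vitellogenin genes had a median log2 difference of −0.07 (camera adjusted p = 0.38), with 1888 ± 294 FPKM in mannose and 1987 ± 144 in water for vit-2. The median was −0.28 with length trends removed (adjusted p = 0.094), −0.13 with upper-quartile scaling, and −0.017 without mannose 1 and water 3. It was −0.015 without mannose 2, −0.11 without mannose 3, −0.12 without water 2 and −0.022 without water 3. Vitellogenins took 3.09 ± 0.592% of reads in mannose and 3.101 ± 0.438% in water (exact permutation p = 1.0). Cuticle collagens took 3.97 ± 0.597% and 5.28 ± 0.312% of reads, ribosomal proteins 15.2 ± 0.320% and 16.13 ± 0.431%, and sperm genes 0.0694 ± 0.0139% and 0.0971 ± 0.00570% (SD, n = 3). For these 3 shares, that of ribosomal RNA (0.260 ± 0.0565% and 0.378 ± 0.0831%) and that of the 100 most read genes (26.8 ± 1.02% and 29.1 ± 0.662%) the exact permutation p was 0.1, the smallest that 3 libraries against 3 allow, and the adjusted p over 9 shares was 0.18. Oocyte and germline genes took 1.08 ± 0.417% and 0.979 ± 0.406% of reads (exact permutation p = 0.8).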

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

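Chosen after the results were seen were the settings without mannose 1 and water 3 together, with a term for them, with length trends removed and without overlapping genes, the smaller pseudocount of 0.5 for genes, and for lists upper-quartile scaling, the looser filters and a pseudocount of 0.1. The count of 0 genes changed by mannose (limma, 532 at an unadjusted p under 0.05) held under 18 of the 20 alternatives. It became 2 without mannose 1, a range of 0 to 2 over the 6 fits that left out 1 library, and 3 without mannose 1 and water 3 (linc-44, dml-1 and pgph-1, the first listed at 0 in mannose 2 and mannose 3). The numbers at an unadjusted p under 0.05 were 713 without those libraries and 1453 with a term for them. With the replicate number as a block the count was 0, with 164 at an unadjusted p under 0.05. Deviations of same-numbered libraries over the tested genes correlated at −0.74, 0.24 and −0.71, so the numbers do not pair the libraries in their largest differences. A smaller effect shared by number could not show in this check. The number of called lists, 16, was 0 with an estimated correlation and 0 with fry, and 11 to 18 with the preset one over the fits without 1 library. Without mannose 3 fry called 2 lists, N-glycosylation and glycosyltransferases (adjusted p = 0.017); in the other settings it called 0. The share of the first component, 67.2%, was 64.2% with a pseudocount of 0.5 and 62.3% with length trends removed. The median of all genes moved by less than 0.1 under each scaling.

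Differences near 0 changed sign. The median of the mannose and nucleotide sugar list was −0.025 with upper-quartile scaling, 0.016 with median-of-ratios scaling, 0.067 without overlapping genes and −0.00040 both without a filter and with a stricter one. The oocyte and germline median was 0.042 with upper-quartile scaling and 0.015 with length trends removed. Without mannose 1 and water 3 the log2 difference was 0.063 for vit-2, 0.0078 for vit-5, 0.024 for hxk-2 and 0.096 for gfat-1. With length trends removed it was 0.030 for F52B11.2 and −0.029 for gfat-2. With 1 library left out the ranges were −0.10 to 0.016 for F52B11.2, −0.83 to 0.86 for gfat-1, −0.16 to 0.39 for gfat-2, −0.12 to 0.40 for gpi-1, −0.44 to 0.10 for hxk-1, −0.32 to 0.33 for hxk-2, −0.082 to 0.39 for hxk-3, −0.0039 to 0.18 for tag-335, −0.17 to 0.050 for vit-2, −0.17 to 0.00058 for the list cytochrome P450, −0.17 to 0.020 for the list lipid binding and transport, −0.19 to 0.60 for the list oocyte and germline, −0.17 to 0.035 for the list oxidative phosphorylation, nuclear and −0.20 to 0.075 for the list ribosomal proteins. The cause was not tested. The planned negative binomial tests were not run, since the values are not counts; limma-voom was run on the read equivalents.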

Other observations

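All of the tests in this part were chosen after the results they bear on were seen. Families of genes with a shared symbol were also compared by the same list test. Some of them share members with the fixed lists, so such calls are not independent of those above. The gst, clec and cyp families hold the same genes as fixed lists, and dnj shares genes with the ER and heat shock lists. The col, msp, rpl, rps and ttr families lie wholly within fixed lists, and ssp and nlp share genes with them. Of 95 families, 20 were called with the preset correlation and 0 with an estimated one (adjusted p at least 0.81 for those named here). The dnj family of DnaJ co-chaperones had a median log2 difference of 0.19 over 29 genes (camera adjusted p = 0.0070) and the vps family of vacuolar sorting genes 0.17 over 30 genes (adjusted p = 0.014). The nlp family of neuropeptide-like genes had −0.12 over 55 genes (adjusted p = 0.0013) and the lec family of galectins −0.15 over 12 genes (adjusted p = 0.012). Of 278 pathways annotated in the tables, 2 were called, Fanconi anemia (0.24 over 26 genes, adjusted p = 0.0067) and protein processing in the endoplasmic reticulum (0.13 over 133 genes, adjusted p = 0.036), each with an adjusted p of 0.89 with an estimated correlation.

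Mannose 1 and water 3 had higher values of oocyte transcripts than the other 4 libraries. The chondroitin proteoglycan gene of the eggshell cpg-1, chosen after its values were seen like the genes that follow, had 468.7 and 664.1 FPKM in these libraries against 50.7 to 58.2 in the others, and lin-41 had 59.9 and 58.0 against 5.56 to 7.02. Of the 45 oocyte and germline genes, 36 lay above the other 4 libraries in both (80%, against 28.6% of all genes), which is consistent with more oocyte RNA, and RNA of part of the germ cells, in them. The values argue against a trend with gene length as the whole cause, since with each library's trend removed the lower of both libraries still exceeded the highest of the others by a median of 0.50 log2 units over these genes. The bootstrap interval, 0.15 to 0.79, came from resampling genes, which vary together, and not libraries. The pattern was not particular to oocyte genes, so oocyte RNA is not shown to be the whole source. Glycolysis genes lay at 0.45 and 0.53 in mannose 1 and water 3 (others −0.42 to −0.033). Tricarboxylic acid cycle genes lay at 0.36 and 0.56 (others −0.35 to −0.17). Other lists went otherwise: body wall muscle genes lay at −0.23 and 0.080 (others −0.11 to 0.16). More embryos were not excluded by the test used: over 15 embryo genes the higher of the medians of both libraries minus the lowest of the other 4 was −0.015 (−0.17 to 0.46, by the same resampling). That statistic tends to lie above 0 where libraries do not differ. The embryo medians of mannose 1 (−0.053) and water 3 (−0.11) were the lowest, against −0.038 to 0.27 in the others, and so gave no sign of more embryos. The other 9 genes were gld-3, glp-1 and genes of meiotic chromosome pairing that differed among themselves: syp-2, syp-3 and him-3 lay below the other 4 libraries in both (him-3 with 133.3 and 121.1 FPKM against 154.1 to 168.7), syp-4 was highest in mannose 1 (62.06 FPKM), and syp-1, htp-1 and htp-2 lay neither above nor below the others in both.

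The lower collagen and sperm genes in mannose may be a response to the sugar, a hypothesis that stays open beside the explanations tested here. Without mannose 1 and water 3 the median log2 difference was −0.60 for sperm genes and −0.28 for collagens, so those libraries were not the whole source. With length trends removed the collagen difference was −0.48, and with reads summed over the list it was −0.44, with no overlap of the groups in either, but summing took away 0.082 of −0.52 with a 95% interval of −0.33 to 0.50, so reads shared between copies stay open for a large part of it. For sperm genes the same values were −0.42 and −0.53, which argues against gene length and against reads shared within the list as the whole cause: of a difference of −0.52 between group means, length removal took away 0.13 (95% interval 0.00049 to 0.26), so a part of it stays open, and summing took away −0.0099 (−0.029 to 0.0090). On the scaled values mannose 1 lay above water 1 and water 2 before and after. As a share of reads it lay below them (0.0821% against 0.0928% and 0.0950%). Of the 10 splits of the libraries into 3 and 3, too few for a share under 0.05, 1, the real one, gave a collagen difference as large as the real one (0.52, highest other 0.42). For sperm genes 2, the real one included, gave a difference as large (0.56, highest other 0.64). A further split, mannose 1, water 1 and water 3 against the rest, nearly reached it, with 0.556 against 0.558.

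The number of called genes and lists was compared over the same 10 splits, which cannot give a share under 0.05. For genes the comparison is void, since each of the 10 splits gives at least the real count of 0. The highest other gave 974, from mannose 1, mannose 2 and water 3 against the rest, which points to a structure of the libraries apart from the treatment. For lists, 2 splits, the real one included, gave at least the real 16, and the highest other gave 19.

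A set of 43 genes had at least 10 FPKM in some library and at least 50 times less in another, such as col-93, with 1188, 1602 and 1855 FPKM in mannose 1, water 2 and water 3 and at most 0.014 in the rest, and its neighbour col-94, with 523 to 885 FPKM in those others. Of them, 41 (95.3%) overlapped another expressed gene on the same strand, against 21.2% of 6787 genes expressed at that level, and in 37 of these 41 the reads summed with the overlapping genes varied by under 3-fold. This is consistent with reads of overlapping gene models being assigned to one model or another from library to library. The groups did not overlap in 5 of the 43 (11.6%, where chance gives 10%), which argues against mannose as the source; dml-1, called without mannose 1, is one of the 43 and overlaps dib-1.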
